A study of Escherichia coli with 12 samples.

How the data were processed

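RNA-seq libraries of 12 samples in 5 groups were compared: nanE.7 and pdxJ.11m with 3 libraries each, and pdxJ.11p, pdxJ.X3p and serB.wt with 2 each. Groups and library numbers were taken from the sample titles. Per the labels' protocols, cells grown in LB were washed and moved to minimal M9-glucose medium, RNA was stabilised at the harvest density, ribosomal RNA was removed with Ribo-Zero, and stranded libraries (NEBNext Ultra II Directional) were sequenced in paired-end mode on a MiSeq. Bowtie2, SAMtools 1.3.1, HTSeq 0.9.1 and DESeq2 are named by the submitters' processing notes, with no settings. The annotation release, the strand setting of the counting and the handling of reads that touch 2 genes are not given in the sources used here, so values of neighbouring his genes, which lie end to end, are not fully separate, and those of genes with an antisense partner are uncertain.

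The deposited count table holds whole-number counts per gene, not normalized, for 4384 genes with gene identifiers; it has 0 columns of other samples. The deposited normalized values (a signal per gene and library) equal those counts divided by 1 size factor per library, and these factors matched DESeq2 size factors computed here from the counts to a largest relative deviation of 5.00e-15, in pdxJ.11m replicate 1; they were used for that check alone. The deposited comparison tables hold log2 fold changes with standard errors, smaller than the log2 ratio of the group means and so shrunken by settings that are not given in the sources used here, and p-values with adjusted p-values, made by the authors for 4 comparisons. The authors' values appear only where the text names their tables. Gene positions are those of the deposited tables, on the E. coli K-12 MG1655 chromosome. Of the 4384 gene symbols 4030 matched a symbol of the reference gene table, and 3983 of these had the same start and end there.

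From the counts, CPM were computed with TMM-scaled library sizes, so they are relative abundances. Genes were kept by the edgeR function filterByExpr with a minimum count of 10 (3166 genes). The main test was the edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust dispersion, 1 mean per group and all 12 libraries in 1 fit, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. This fit had 7 residual degrees of freedom. The 7 comparisons were chosen before the data were examined: 4 of a variant with serB.wt, pdxJ.11p with pdxJ.11m, and 2 between other variants. Values are given as mean ± SD of CPM over libraries and as log2 fold change ± SE.

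A set of 32 gene lists of textbook pathways and regulons was fixed together with the comparisons; of their 621 genes 610 were in the files and 522 were tested. Each list was tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison, and members were counted both over all genes tested and adjusted over the list alone. Lists that passed camera held with an estimated correlation in 1 of 11 cases for nanE.7, 5 of 8 for pdxJ.11p, 4 of 12 for pdxJ.X3p, 1 of 12 for pdxJ.11m (each against serB.wt), 3 of 16 for pdxJ.11p against pdxJ.11m, 0 of 16 for nanE.7 against pdxJ.11p and 0 of 8 for pdxJ.X3p against pdxJ.11p. With serB, nanE, pdxJ and the his genes removed from the lists, a variant added after the data had been seen, these were 0 of 7, 2 of 5, 2 of 7, 1 of 9, 0 of 14, 0 of 13 and 0 of 6. A further 7 lists were chosen after the data had been seen, and 4 of them appear in the closing observations only.

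The genes named follow a rule fixed at the same time: serB, nanE and pdxJ; for each of the first 5 comparisons up to 6 genes each way with the largest change among called genes whose CPM ranges do not overlap and whose mean reaches 50 CPM in the higher group; the 8 his genes, serA, serC, gph and ytjC; and the 3 members with the smallest adjusted p of each list that passed camera. Between variants up to 3 genes each way plus hisB and hisC were taken. With groups of 2 and 3 many genes separate by chance, so this condition alone is weak. Genes named outside the rule (such as hisL, pspB, pspD and pspE where they fall outside it, csgB, wcaK, wcaL and wcaM between variants, adhE, fnrS, and the lists chosen later) were chosen after their values were seen.

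Total counts of 521412 to 844637 per library limit the precision for weakly expressed genes. The steps were tested on simulated data drawn from the observed means, library sizes and dispersions, with a single draw for each comparison and set of libraries. For nanE.7 against serB.wt over 3166 genes with 12 libraries, 13 of 100 genes changed by 1 log2 unit and 86 of 106 changed by 2 log2 units were recovered with 4 false calls; with 10 libraries (3090 genes) these were 80 of 100 and 103 of 108 with 4 false calls. For pdxJ.11p against serB.wt with 12 libraries 7 of 100 and 76 of 108 were recovered, with 3 false calls over 3166 genes; with 10 libraries 71 of 100 and 104 of 107 were recovered, with 15 false calls among 190. For pdxJ.11p against pdxJ.11m there were 5 false calls among 106 with 12 libraries and 10 among 188 with 10. In these last 2 comparisons the 10-library share of false calls was thus above the threshold of 0.05. DESeq2 on the same simulated 12 libraries made 13 false calls among 127 for nanE.7 and 10 among 103 for pdxJ.11p against serB.wt, and 17 among 120 for pdxJ.11p against pdxJ.11m, more than edgeR in each case. With 10 libraries DESeq2 made 2 among 160, 4 among 154 and 2 among 155.

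Alternatives fixed beforehand were DESeq2 size factors, no expression filter, a minimum count of 50, the DESeq2 1.42.0 Wald test, the library number as a block, a fit of only the groups compared, serB, nanE and pdxJ left out, and each library left out in turn. Fits without the 2 libraries numbered 3, by edgeR and by DESeq2, were added after the data had been seen, as was a fit with 1 serB.wt library for each of 2 comparisons. Replicate libraries differed by more than sampling noise: the closest pair, nanE.7 replicates 1 and 2, had a chi-square of 1.22 per degree of freedom (p = 5.19e-17), which does not tell separate cultures from repeated preparations of 1 culture.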

Results

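The series holds 12 RNA-seq libraries of Escherichia coli BW25113, a K-12 laboratory strain, grown in minimal M9-glucose medium at 30 °C to an optical density of 0.5. The cells of 4 groups carried modified (βα)8-barrel proteins, an enzyme fold in which 8 strands form a central barrel ringed by helices, and the labels name these groups nanE.7 (n = 3), pdxJ.11m (n = 3), pdxJ.11p (n = 2) and pdxJ.X3p (n = 2). NanE is an epimerase of sialic acid breakdown and PdxJ makes pyridoxine phosphate, a form of vitamin B6. The fifth group, serB.wt (n = 2), is the reference of the deposited comparisons, and SerB is the phosphatase that completes serine synthesis. The labels do not say what the letters p and m in the names stand for. The comparisons ask which genes differed between cells with each variant and the serB.wt cells, and between variants. Total counts ran from 521412 to 844637 per library over 4384 genes, of which 3166 passed the expression filter. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples.

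The gene named in each group label stood far above its level in the groups not named for it. Counts of nanE reached 16008 ± 2921 CPM (mean ± SD, n = 3) in nanE.7 against 9.19 ± 0.88 (n = 2) in serB.wt. Counts of pdxJ reached 17626 ± 6793 CPM in pdxJ.11m (n = 3), 31154 ± 2832 in pdxJ.11p (n = 2) and 47509 ± 3690 in pdxJ.X3p (n = 2), against 122 ± 11.96 in serB.wt (n = 2). Counts of serB stood at 22778 ± 1264 CPM in serB.wt (n = 2), and group means elsewhere lay between 95.2 ± 42.6 in nanE.7 (n = 3) and 125 ± 24.1 in pdxJ.11p (n = 2), from 22 to 107 counts per library. These counts cannot separate a chromosomal copy of a gene from an introduced one.

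The 2 libraries numbered 3, one of nanE.7 and one of pdxJ.11m, stood apart from the other 10 along the first principal component, which held 59.0% of the variance. Transcripts of fermentation and anaerobic growth were high in both. The alcohol dehydrogenase gene adhE stood at 33946 and 30912 CPM against 3134 to 4812 in the other 10 libraries, and the small RNA fnrS at 747 and 1361 against 1.56 to 14.8. All 22 measured genes for anaerobic respiration and fermentation were higher in library 3 than in the mean of libraries 1 and 2 of the same group, with log2 medians of 2.12 (SD 0.89 over genes) in nanE.7 and 1.87 (SD 1.03 over genes) in pdxJ.11m. Purine synthesis genes had medians of -3.05 and -2.51, TCA cycle genes -2.28 and -2.18, heat shock genes 0.96 and 1.07, and the his operon 0.78 and 0.94. Each of these differences sets 1 library against 2 and has no test. The common coefficient of biological variation was 0.312 over all 12 libraries and 0.0918 over the 10 without number 3. The main test used all 12 libraries, and each comparison is also given for the 10 libraries, a choice made after the data had been seen. The libraries numbered 3 include no serB.wt sample and 1 sample of each of 2 groups, so they give no comparison of their own.

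**Figure D1:**
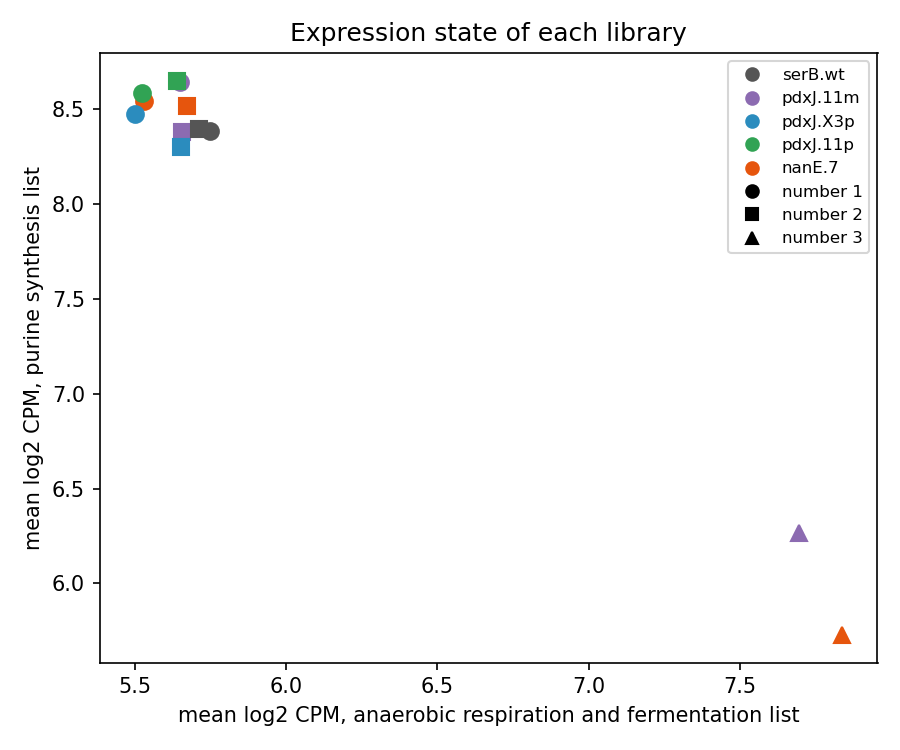
Mean log2 CPM of the genes for anaerobic respiration and fermentation (x axis) against that of the purine synthesis genes (y axis) in each of the 12 libraries, coloured by group, with the marker giving the library number. The libraries numbered 3 lie at 7.84 and 7.70 on the x axis, and the other 10 between 5.50 and 5.75.

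In nanE.7 cells the his operon, whose 8 genes encode the enzymes of histidine synthesis, stood far above its level in serB.wt cells. All 8 measured genes rose, from hisH by a log2 fold change of 3.73 ± 0.42 (SE) to hisD by 4.50 ± 0.42. Among them hisB, which encodes the histidinol-phosphate phosphatase, rose from 265 ± 53.1 (n = 2) to 5017 ± 1843 CPM (n = 3) (log2 4.24 ± 0.40, edgeR quasi-likelihood adjusted p = 0.000655), and hisC, the histidinol-phosphate aminotransferase, from 297 ± 39.6 to 6042 ± 2610 CPM (log2 4.34 ± 0.41, edgeR adjusted p = 0.000655). Genes for colanic acid, an exopolysaccharide of the cell surface, fell together with yjbE of another exopolysaccharide locus: cpsB fell by 1.88 ± 0.24, wcaK fell by 1.83 ± 0.24, wcaL fell by 1.81 ± 0.25, wcaM fell by 1.57 ± 0.16 and yjbE fell by 2.27 ± 0.29 on the log2 scale. The curli gene csgB had 2 counts over the nanE.7 libraries and 36 over the serB.wt libraries, a ratio of 0.0383 with a 95% counting interval of 0.00447 to 0.149.

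The operon lies on the plus strand of the E. coli K-12 MG1655 chromosome, from hisL at 2089996 to the end of hisI at 2097225, and hisB (EG10445) covers 2093468 to 2094535. The leader gene hisL rose by 2.43 ± 0.44 (edgeR adjusted p = 0.0453). Over all genes 10 rose and 7 fell in nanE.7 against serB.wt, nanE and serB included, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p under 0.05. The summed his operon made up 34035 ± 13438 CPM in nanE.7 (n = 3) and 1780 ± 179 in serB.wt (n = 2). Its median log2 fold change was 4.17, all 8 genes passed over all genes tested and 8 adjusted over the list alone (camera adjusted p = 0.0101 with an estimated correlation). Serine synthesis genes outside serB did not pass with 12 libraries, with serA at 0.48 ± 0.20 and serC at 0.22 ± 0.22, nor did the phosphatase genes gph at 0.20 ± 0.20 and ytjC at 0.27 ± 0.20.

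Of the 19 envelope stress genes 0 passed the edgeR test over all genes in nanE.7, where 293 of all genes had an unadjusted p under 0.05 and DESeq2 called 33, and 8 passed adjusted over the list alone. Of these, 7 were lower, and pspA stood at -1.55 ± 0.34 and pspC at -1.51 ± 0.32 (adjusted p = 0.152 with an estimated correlation). In the 4-member list of phosphatases that can replace SerB, hisB alone rose (adjusted p = 0.103 with an estimated correlation), and in the sialic acid list nanE alone rose over all genes (adjusted p = 0.407 with an estimated correlation). The other 7 lists that passed with the preset correlation had no gene past the threshold and adjusted p from 0.588 to 0.743 with an estimated correlation. They included arginine synthesis and transport at a median of -0.56, with argA at -1.04 ± 0.42 and artJ at -1.06 ± 0.47, ribosomal proteins at -0.32, and the genes for anaerobic growth at 1.08, which were high in library 3. The arginine and ribosomal lists were low in library 3, with medians of -1.37 and -0.57 against libraries 1 and 2. Without the libraries numbered 3 the arginine median against serB.wt was -0.26.

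Without the libraries numbered 3, 244 genes changed in nanE.7 against serB.wt, 117 up and 127 down, by the same edgeR test. The his operon median was then 3.89, and the summed operon of nanE.7 was 26277 ± 132 CPM (n = 2). Within those 10 libraries 11 of 17 TCA cycle genes rose and 1 fell (adjusted p = 0.213 with an estimated correlation), and 12 of 20 heat shock genes fell and 1 rose (adjusted p = 0.205 with an estimated correlation). Of the 19 envelope stress genes 9 fell and 1 rose there (adjusted p = 0.213 with an estimated correlation), with pspC fallen by 1.35 ± 0.22. In the same fit serA rose by 0.50 ± 0.13, and 4 of 7 serine and glycine genes rose adjusted over the list alone (adjusted p = 0.381 with an estimated correlation). Without serB.wt replicate 1 the 12-library count of 17 became 9, and without serB.wt replicate 2 it became 10; hisA, hisH, hisF, hisI and hisL lost their calls both times, yjbE, cpsB and csgB in the first and wcaK and wcaL in the second. The hisL call was also lost without any single nanE.7 replicate, and csgB without nanE.7 replicate 2. Without serB.wt replicate 1 or replicate 2 the his operon median was 4.06 and 4.27.

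**Figure D2:**
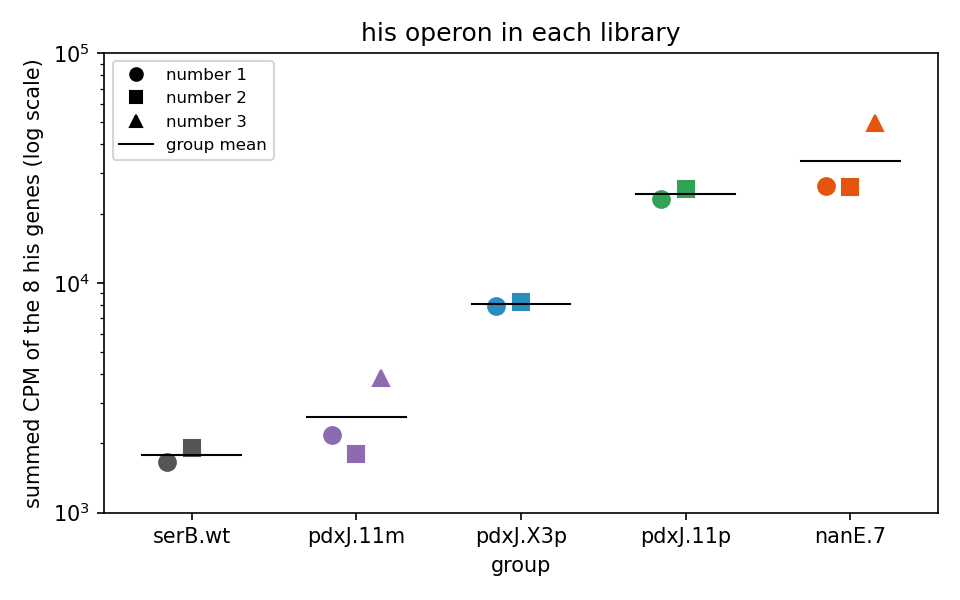
Summed CPM of the 8 his operon genes in each library (log axis), by group, with the marker giving the library number and the line the group mean. The serB.wt libraries lie at 1654 and 1906, those of pdxJ.X3p at 7938 and 8249, those of pdxJ.11p at 23150 and 25693, and those of nanE.7 between 26183 and 49552.

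**Figure D3:**
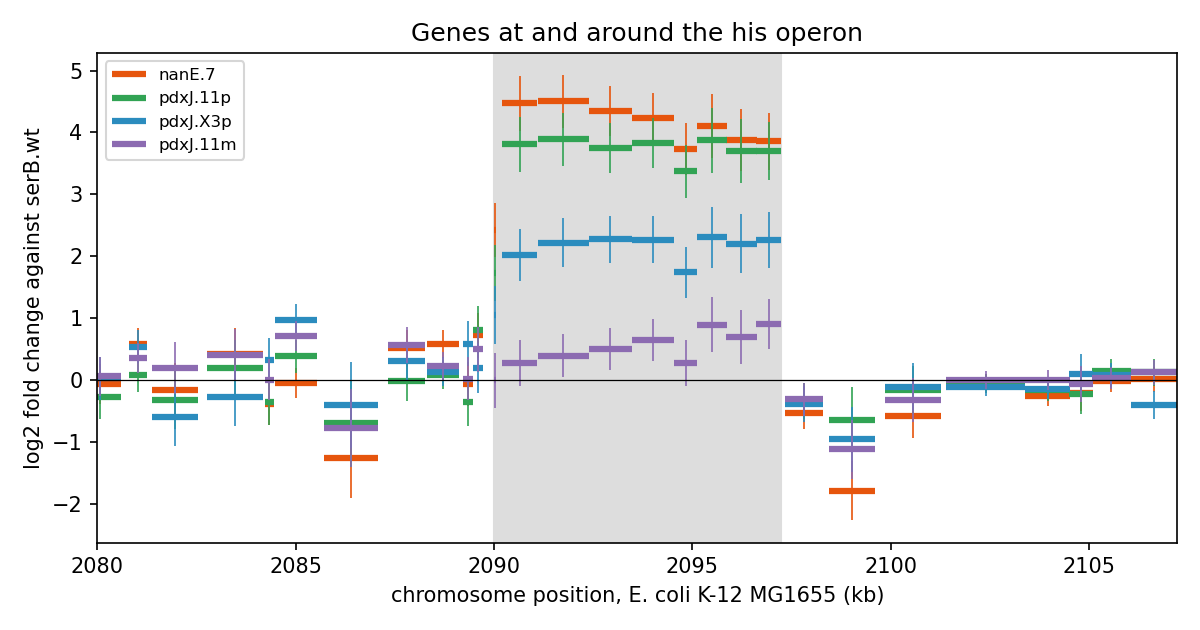
Log2 fold change against serB.wt (y axis, vertical lines are SE) of the tested genes within 10 kb of the his operon, at their chromosome positions in kb (x axis), for 4 groups, all 12 libraries. The shaded span is the operon with its leader; the 19 tested neighbours had median log2 fold changes of -0.07 in nanE.7, -0.16 in pdxJ.11p and 0.03 in pdxJ.X3p.

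In pdxJ.11p cells the same operon rose against serB.wt. All 8 his genes passed, from hisH (log2 3.37 ± 0.43) to hisD (3.89 ± 0.42), and hisB rose to 3771 ± 224 CPM (n = 2, log2 3.83 ± 0.41, edgeR adjusted p = 0.00221) and hisC to 4010 ± 382 (n = 2, log2 3.75 ± 0.41, edgeR adjusted p = 0.00221). The phage shock genes pspA and pspC, of a response to inner membrane damage, were lower: pspA fell by 2.63 ± 0.40 and pspC fell by 2.47 ± 0.39 on the log2 scale (edgeR adjusted p = 0.0194 and 0.0209). The level of pspA was 378 ± 133 CPM in pdxJ.11p and 2345 ± 852 in serB.wt, with 2 libraries each.

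Over all genes 9 rose and 3 fell in pdxJ.11p against serB.wt by the edgeR test, pdxJ and serB included. The his operon had a median log2 fold change of 3.78 and 24422 ± 1798 summed CPM (n = 2), with 8 of 8 genes also passing adjusted over the list alone (camera adjusted p = 0.00232 with an estimated correlation). Of the 19 envelope stress genes 2 fell, pspA and pspC, and 6 fell adjusted over the list alone (median -0.14, adjusted p = 0.0111 with an estimated correlation). Acid resistance genes had a median of -0.71; none of 13 passed over all genes and 4 fell adjusted over the list alone (adjusted p = 0.00865 with an estimated correlation). Examples are mdtF of a drug efflux pump at -1.02 ± 0.18 and gadB at -0.74 ± 0.22; gadB and gadA are near-identical copies, so their counts are uncertain. In the vitamin B6 list pdxJ alone rose (adjusted p = 0.0106 with an estimated correlation), and in the phosphatase list hisB alone (adjusted p = 0.0111 with an estimated correlation).

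Heat shock genes had a median of -0.67 in pdxJ.11p, with rpoH at -0.75 ± 0.16 and htpX at -0.70 ± 0.18 (adjusted p = 0.438 with an estimated correlation). TCA cycle genes had a median of 0.64, with sucC at 1.07 ± 0.74 (adjusted p = 0.911 with an estimated correlation), and aminotransferases 0.26, with alaC at 0.62 ± 0.19 and hisC the member that rose (adjusted p = 0.18 with an estimated correlation). The values of serA (0.61 ± 0.22), serC (0.33 ± 0.24), gph (0.33 ± 0.22) and ytjC (0.30 ± 0.22) did not pass. Without the libraries numbered 3, which belong to neither group, 152 genes changed, 79 up and 73 down. In that fit 14 of 20 heat shock genes fell (adjusted p = 0.0462 with an estimated correlation, and 0.112 when the lists lack the his genes and serB, nanE and pdxJ), 8 of 13 acid resistance genes fell (adjusted p = 0.0746 with an estimated correlation) and 13 of 17 TCA cycle genes rose while 1 fell (adjusted p = 0.0746 with an estimated correlation). There sucC rose by 1.06 ± 0.13 and serA by 0.61 ± 0.13. With serB.wt replicate 1 or replicate 2 left out of the 12, the count of 12 became 2 both times and all 8 his calls were lost, with medians of 3.66 and 3.89; the lone control is then assumed to vary like the other groups. The pspA call was also lost without pdxJ.11p replicate 1 or replicate 2, the pspC call without replicate 1 and the hisF call without replicate 2.

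In pdxJ.X3p cells the his operon stood at an intermediate level, 8093 ± 220 summed CPM (n = 2), and the gene flu rose. The his median against serB.wt was 2.24 on the log2 scale; hisB (2.26 ± 0.38) and hisC (2.27 ± 0.38) passed over all genes (edgeR adjusted p = 0.0356 for both), and 8 of 8 passed adjusted over the list alone (camera adjusted p = 0.0147 with an estimated correlation). The gene flu, which encodes antigen 43, an autoaggregation protein of the outer membrane, rose from 91.0 ± 2.12 (n = 2) to 836 ± 29.3 CPM (n = 2) (log2 3.20 ± 0.23, edgeR adjusted p = 9.43e-05). The phage shock genes fell as a set: pspG fell by 5.29 ± 0.68, pspA fell by 4.62 ± 0.44, pspC fell by 4.06 ± 0.44, pspD fell by 3.87 ± 0.58, pspE fell by 3.43 ± 0.50 and pspB fell by 3.17 ± 0.52 on the log2 scale. Their median was below that of serB.wt in every variant group, so a raised level in the serB.wt cells cannot be told from a fall. The small chaperone gene ibpB fell by 4.71 ± 0.71 and the membrane protease gene htpX fell by 1.11 ± 0.18.

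Over all genes 4 rose and 9 fell in pdxJ.X3p against serB.wt by the edgeR test. Of the 19 envelope stress genes 6 fell, the phage shock genes, and 7 fell adjusted over the list alone (median -0.22, adjusted p = 0.00769 with an estimated correlation). Of 20 heat shock genes 2 fell over all genes and 4 adjusted over the list alone (median -0.63, adjusted p = 0.362 with an estimated correlation). Acid resistance genes had a median of -0.70; none of 13 passed over all genes and 5 fell adjusted over the list alone (adjusted p = 0.0147 with an estimated correlation). One member passed in each of the vitamin B6 (pdxJ), serine and glycine (serB), prophage (flu) and phosphatase (hisB) lists, with adjusted p = 0.0147, 0.362, 0.162 and 0.145 with an estimated correlation. Sulfate assimilation genes had a median of 0.44, with cysH at 0.77 ± 0.26 (adjusted p = 0.379 with an estimated correlation), and aromatic amino acid genes -0.17, with aroF at -1.24 ± 0.59 and tyrA at -1.19 ± 0.55 (adjusted p = 0.54 with an estimated correlation). Phosphate starvation genes stood at 0.40 (adjusted p = 0.54 with an estimated correlation) and TCA cycle genes at 0.61 (adjusted p = 0.925 with an estimated correlation). The value of serA was -0.08 ± 0.21.

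In the 10-library fit 207 genes changed in pdxJ.X3p against serB.wt, 100 up and 107 down. All 8 his genes rose, 13 of 20 heat shock genes fell (adjusted p = 0.0448 with an estimated correlation, and 0.0868 when the lists lack the his genes and serB, nanE and pdxJ), 8 of 13 acid resistance genes fell (adjusted p = 0.0951 with an estimated correlation), and 11 of 17 TCA cycle genes rose while 1 fell (adjusted p = 0.0951 with an estimated correlation). The 12-library count of 13 became 4 without pdxJ.X3p replicate 1 or replicate 2, 5 without serB.wt replicate 1 and 7 without serB.wt replicate 2. The calls of hisB, hisC, ibpB, htpX, pspB and pspD were lost in each of these 4 fits, those of pspE and pspG in all but the fit without serB.wt replicate 2, and that of pspC without either pdxJ.X3p replicate. In the same order of fits the his operon median was 2.29, 2.21, 2.14 and 2.33.

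**Figure D4:**
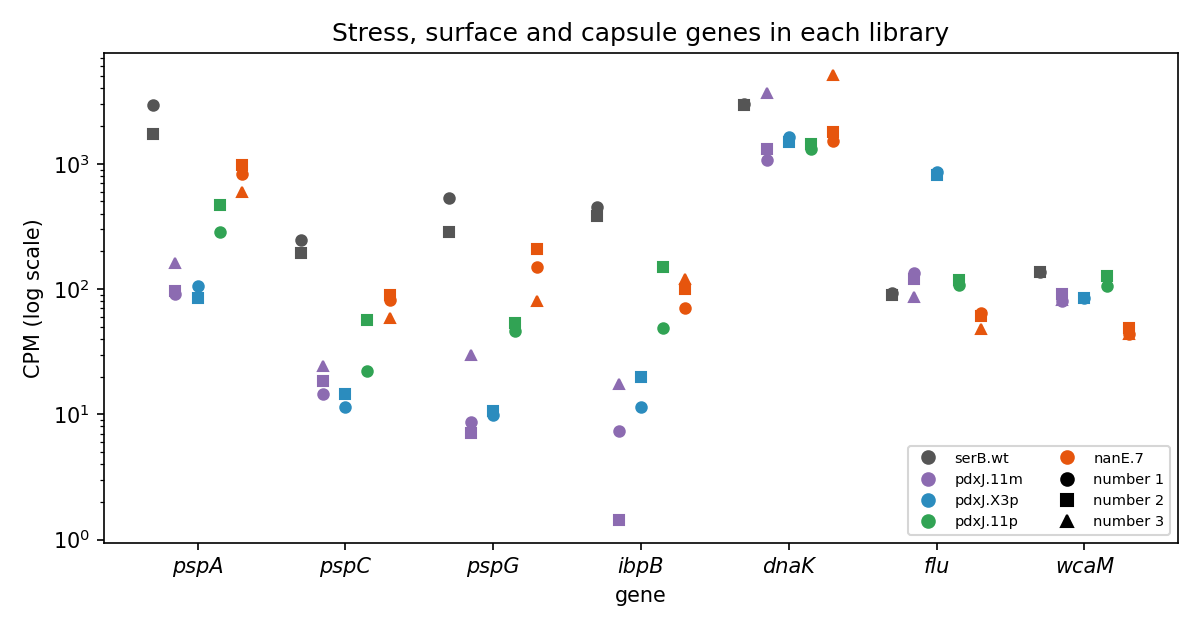
CPM of 7 genes (log axis) in each of the 12 libraries, coloured by group, with the marker giving the library number. In both serB.wt libraries pspA, pspC, pspG and ibpB lie above all other libraries, and flu lies above the other groups in both pdxJ.X3p libraries.

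Between pdxJ.11p and pdxJ.11m, a contrast of the deposited tables, the his operon differed and no other gene passed. All 8 his genes rose in pdxJ.11p relative to pdxJ.11m, from hisI (2.80 ± 0.39) to hisG (3.53 ± 0.38), with hisB at 3.18 ± 0.34 and hisC at 3.25 ± 0.34 (edgeR adjusted p = 0.0023 for both). The summed operon was 24422 ± 1798 CPM in pdxJ.11p (n = 2) and 2609 ± 1084 in pdxJ.11m (n = 3), where library 3 had the highest value, 3842. By the edgeR test 8 genes rose and 0 fell; 125 genes had an unadjusted p under 0.05, and DESeq2 called 14. The pdxJ level itself did not pass, at 0.82 ± 0.31.

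The his operon median between pdxJ.11p and pdxJ.11m was 3.14, with 8 of 8 genes passing adjusted over the list alone (camera adjusted p = 0.00242 with an estimated correlation). Acid resistance genes had a median of -0.53; none of 13 passed over all genes and 1 fell adjusted over the list alone (adjusted p = 0.0216 with an estimated correlation), with mdtF at -0.86 ± 0.17. With the his genes, serB, nanE and pdxJ removed from the lists, a step added after the data had been seen, the value was 0.0627 and the acid resistance list did not pass. In the phosphatase list hisB alone rose (adjusted p = 0.0216 with an estimated correlation). In the sulfur list 8 of 24 genes fell adjusted over the list alone and none over all genes (median -0.33, adjusted p = 0.176 with an estimated correlation). Its members for use of taurine and alkanesulfonates as sulfur sources included ssuA at -2.93 ± 0.57, tauC at -2.57 ± 0.66 and tauB at -2.42 ± 0.61. Nitrogen assimilation genes had a median of -0.61, with 2 lower adjusted over the list alone, and nac stood at -1.72 ± 0.37 and amtB at -1.39 ± 0.35 (adjusted p = 0.17 with an estimated correlation). Serine and glycine genes had a median of 0.45, with serA at 0.61 ± 0.19 and gcvH at 0.68 ± 0.19 (adjusted p = 0.176 with an estimated correlation). The other 10 lists that passed with the preset correlation had adjusted p from 0.17 to 0.688 with an estimated correlation, and their only member past the threshold over all genes was hisC, an aminotransferase. Adjusted over the list alone, 4 of 15 aromatic amino acid genes fell and 1 of 19 envelope stress genes rose.

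Without the libraries numbered 3, 42 genes differed between pdxJ.11p and pdxJ.11m, 20 up and 22 down, and the his operon median was 3.59. There pdxJ was higher in pdxJ.11p by 0.52 ± 0.11 (edgeR adjusted p = 0.0148), and ssuA fell by 3.05 ± 0.55, nac fell by 1.83 ± 0.32 and amtB fell by 1.35 ± 0.27. The 12-library count of 8 became 4 without pdxJ.11m replicate 1, 5 without pdxJ.11p replicate 1 and 4 without pdxJ.11p replicate 2, with hisF, hisA and hisI lost each time and hisH in the first and last of these. In an edgeR fit of the libraries of these groups alone it was 0, with 67 genes at an unadjusted p under 0.05, while DESeq2 on all 12 called 14. The his operon median in the fit of these groups alone was 3.13.

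In pdxJ.11m cells the phage shock genes were low and no his gene passed against serB.wt. The chaperone gene ibpB fell by 5.61 ± 0.65, pspG fell by 4.79 ± 0.56, pspB fell by 4.46 ± 0.52, pspA fell by 4.33 ± 0.37 (edgeR adjusted p = 0.000415), pspC fell by 3.52 ± 0.36, pspE fell by 3.36 ± 0.44 and pspD fell by 3.25 ± 0.48 on the log2 scale. The his genes ranged from 0.28 ± 0.37 for hisG to 0.90 ± 0.41 for hisI, with hisB at 0.65 ± 0.34. By the edgeR test pdxJ alone rose and 8 genes fell.

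The his operon median in pdxJ.11m was 0.58; none of 8 genes passed over all genes or adjusted over the list alone (adjusted p = 0.666 with an estimated correlation). Of 19 envelope stress genes 6 fell, the phage shock genes (median -0.08, adjusted p = 0.0107 with an estimated correlation), and of 20 heat shock genes 1 fell over all genes and 5 adjusted over the list alone (median -0.23, adjusted p = 0.477 with an estimated correlation). Sulfur genes had a median of 0.38, with 3 higher adjusted over the list alone, and ssuA stood at 2.21 ± 0.53, tauB at 2.51 ± 0.62 and ssuD at 2.85 ± 0.76 (adjusted p = 0.47 with an estimated correlation). In the vitamin B6 list pdxJ alone rose (adjusted p = 0.0831 with an estimated correlation), and in the serine and glycine list serB alone fell (adjusted p = 0.135 with an estimated correlation). The other 6 lists that passed with the preset correlation had no gene past the threshold and adjusted p from 0.376 to 0.753 with an estimated correlation.

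In the 10-library fit 154 genes changed in pdxJ.11m against serB.wt, 80 up and 74 down. The his operon median was then 0.20, and the summed operon of pdxJ.11m was 1992 ± 266 CPM (n = 2). In that fit 14 of 20 heat shock genes fell (adjusted p = 0.0194 with an estimated correlation) and 13 of 17 TCA cycle genes rose while 1 fell (adjusted p = 0.0483 with an estimated correlation). With the his genes, serB, nanE and pdxJ removed from the lists these values were 0.0281 and 0.0584, so the TCA cycle list no longer passed. In the 12-library fit pspD lost its call without pdxJ.11m replicate 1 or either serB.wt replicate, and pspE without pdxJ.11m replicate 1 or serB.wt replicate 1.

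**Figure D5:**
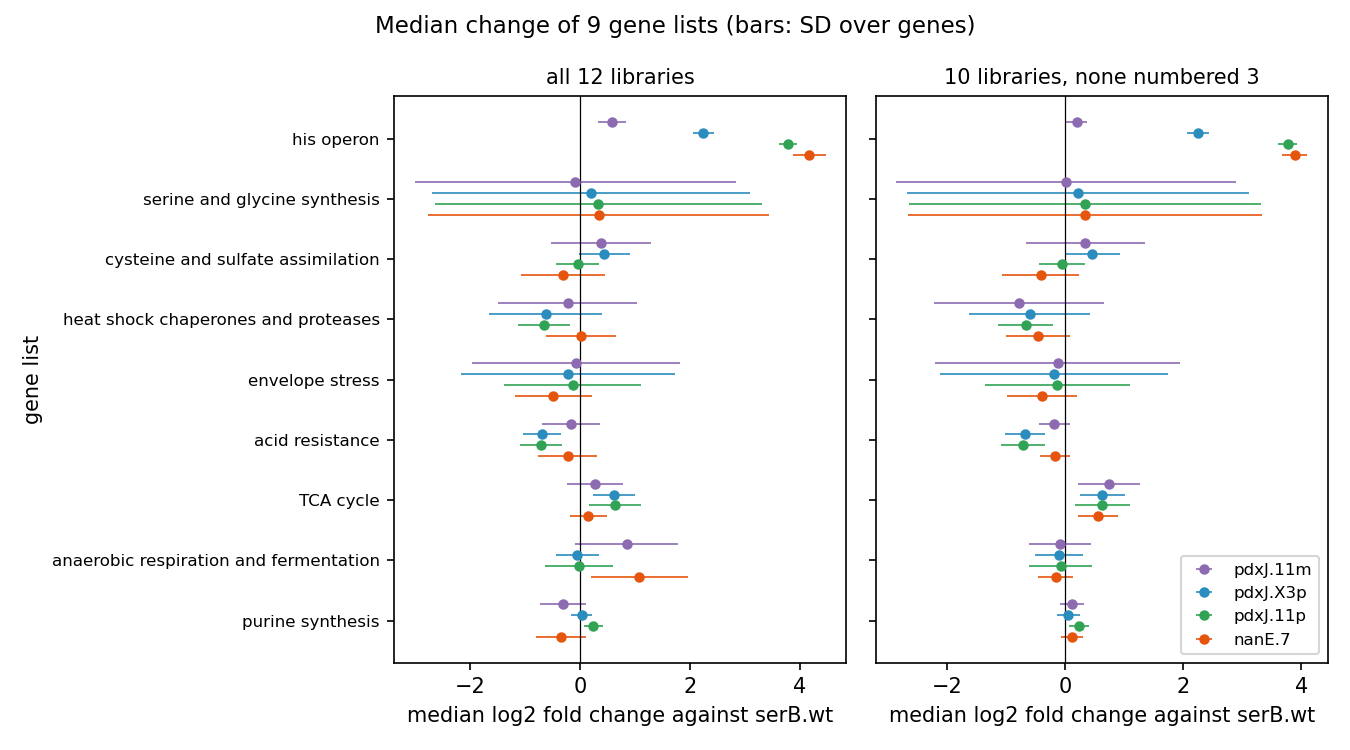
Median log2 fold change against serB.wt (x axis) of 9 gene lists (y axis) for the 4 variant groups, with all 12 libraries on the left and without the libraries numbered 3 on the right; bars are the SD over the genes of a list. The his operon medians run from 0.58 to 4.17 on the left, where the anaerobic list lies at 1.08 for nanE.7 and 0.85 for pdxJ.11m, the groups with a library numbered 3.

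Between variants, 4 of 20 colanic acid genes and 2 of 6 curli genes were lower in nanE.7 than in pdxJ.11p, and 20 and 4 adjusted over the list alone (adjusted p = 0.0126 for both lists with an estimated correlation). Both lists were chosen after the data had been seen. Of the colanic acid genes, cpsB (64.1 ± 12.1 CPM, n = 3, against 212 ± 19.1, n = 2) fell by 1.72 ± 0.24, wcaK fell by 1.71 ± 0.24, wcaL fell by 1.64 ± 0.25 and wcaM fell by 1.33 ± 0.16 on the log2 scale. The gene csgA, for the main subunit of curli fibres, fell by 2.52 ± 0.42 (edgeR adjusted p = 0.0496). The his genes hisB at 0.41 ± 0.33 and hisC at 0.59 ± 0.34 did not pass between these groups, and the his median was 0.38 (adjusted p = 0.651 with an estimated correlation). Including nanE and pdxJ, 1 gene rose and 7 fell in nanE.7 by the edgeR test, and 57 changed without the libraries numbered 3, where csgA did not pass (edgeR adjusted p = 0.177). Leaving out nanE.7 replicate 1, 2 or 3 gave 2, 3 and 3 genes and leaving out pdxJ.11p replicate 1 or 2 gave 3 and 2. In each case csgA, csgB, cpsB, wcaK and wcaL lost their calls, and wcaM did where 2 genes were left, nanE and pdxJ.

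Between pdxJ.X3p and pdxJ.11p, flu was higher in pdxJ.X3p by 2.88 ± 0.23 on the log2 scale (edgeR adjusted p = 0.000637) and was the 1 gene called. The his operon had a median of -1.56, with hisB at -1.56 ± 0.37 and hisC at -1.48 ± 0.37; by the edgeR test 0 of 8 genes passed over all genes and 8 of 8 adjusted over the list alone (camera adjusted p = 0.0874 with an estimated correlation), while 80 of all genes had an unadjusted p under 0.05 and DESeq2 called 2. Without the libraries numbered 3, which belong to neither group, 32 genes differed and all 8 his genes fell (median -1.54, adjusted p = 0.00724 with an estimated correlation), where hisB fell by 1.54 ± 0.11 and hisC fell by 1.45 ± 0.11.

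The genes called in the same direction in nanE.7, pdxJ.11p and pdxJ.X3p against serB.wt were hisB, hisC and serB in the 12-library fit, and 71 genes without the libraries numbered 3. These comparisons share the 2 serB.wt libraries. In 40 simulated sets of unchanged groups with the same controls, the mean number shared by all 3 was 0 for the 12-library fit and 0.05 for the 10-library fit. In the 10-library fit nanE.7 and pdxJ.11p shared 53 genes that rose, against 2.99 for independent lists of the same lengths, and 49 that fell. For nanE.7 and pdxJ.X3p these were 45 and 59, against 3.79 and 4.398, and for pdxJ.11p and pdxJ.X3p 40 and 56, against 2.56 and 2.53. In that fit the covariances of log2 fold changes across genes, which are not independent replicates, were 0.165, 0.146 and 0.170 for these pairs, against simulated values of 0.0458, 0.0457 and 0.0451. In the 12-library fit they were 0.170, 0.128 and 0.172 against simulated values of 0.154, 0.156 and 0.155. With serB, nanE, pdxJ and the his genes left out, the 12-library values were 0.113, 0.0849 and 0.113, below the simulated ones, and the 10-library values were 0.110, 0.105 and 0.109, above them. The 12-library simulations gave the serB.wt libraries the wider spread that the libraries numbered 3 bring (common coefficient of biological variation 0.312 against 0.0918). Their values may thus be too high, and lying below them says nothing about overlap. A fit added after the data had been seen gave each comparison of a pair its own serB.wt library, both ways round. With the same genes left out its covariances were then 0.0669 and 0.0745, 0.0715 and 0.0619, and 0.0799 and 0.0628 in the 10 libraries, and from 0.0414 to 0.0815 in the 12. In 40 simulated sets of unchanged groups split in this way the highest covariance was 0.0148 for the 10 libraries and 0.0578 for the 12. The labels do not say whether the 2 serB.wt libraries came from separate cultures, so giving each comparison its own library need not remove all that the controls share, and how much of the overlap comes from them stays open. These comparisons also cannot tell a change shared by the variants from a change in the serB.wt cells. The same limit holds for TCA cycle and heat shock genes, which moved mostly the same way in every variant group in the 10-library fit. Without serB.wt replicate 1 or replicate 2, or without either pdxJ.X3p replicate, nanE.7 replicate 1 or pdxJ.11p replicate 1, the 12-library number of 3 became 1, serB, and without nanE.7 replicate 3 it became 6.

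The authors' deposited tables called 34 genes for nanE.7, 20 for pdxJ.11p and 22 for pdxJ.X3p against serB.wt, and 16 between pdxJ.11p and pdxJ.11m, at the same threshold of 0.05. All 17, 12, 13 and 8 genes called here with 12 libraries were among them. For hisB the authors' deposited tables list log2 fold changes of 3.35 in nanE.7, 2.91 in pdxJ.11p and 1.67 in pdxJ.X3p against serB.wt, each smaller than the value fitted here.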

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

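Of the tests given here, those of exchanged sample labels, transgene dose, an amplified region, other amino acid lists and reads assigned to a wrong library were chosen after the result was seen, as were all fits without the libraries numbered 3.

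Effects against the same reference differed between variants by a direct test in the edgeR fit of all 12 libraries. Between pdxJ.11p and pdxJ.11m the 8 his genes differed, with log2 values of 2.80 ± 0.39 (SE) for hisI, 2.98 ± 0.43 for hisA, 3.01 ± 0.42 for hisF, 3.09 ± 0.36 for hisH, 3.18 ± 0.34 for hisB, 3.25 ± 0.34 for hisC, 3.49 ± 0.35 for hisD and 3.53 ± 0.38 for hisG. Between nanE.7 and pdxJ.11p the values were -2.52 ± 0.42 for csgA, -1.72 ± 0.24 for cpsB, -1.71 ± 0.24 for wcaK, -1.64 ± 0.25 for wcaL and -1.33 ± 0.16 for wcaM. The fitted value of csgB in that comparison was -4.90, but it rests on 2 counts in nanE.7 against 50 in pdxJ.11p, a ratio of 0.0284 with a 95% counting interval of 0.00335 to 0.108. With any single library of these groups left out, csgA, csgB, cpsB, wcaK and wcaL lost their calls. The csgA call was also lost without the libraries numbered 3. Library 3 of nanE.7 was itself lower than libraries 1 and 2 in colanic acid genes (median -1.29) and curli genes (-1.05). Without number 3 the colanic acid median in this comparison was still -1.79. Between pdxJ.X3p and pdxJ.11p, flu differed by 2.88 ± 0.23. Without the libraries numbered 3 the his operon also differed between pdxJ.X3p and pdxJ.11p, with a median of -1.54 (camera adjusted p = 0.00724 with an estimated correlation).

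The libraries numbered 3 of nanE.7 and pdxJ.11m stood apart from the other 10. Library depth is argued against: with every library thinned to 521412 counts the anaerobic list still had medians of 1.88 and 1.76. For the nanE.7 library an exchange of labels with another group is argued against. There nanE stood at 1376 times its serB.wt mean, and no library outside nanE.7 had more than 10 nanE counts. For the pdxJ.11m library an exchange was not excluded: pdxJ stood at 81.8 times its serB.wt mean, but it is also high in 2 other groups. It held 0.96% of counts in this library, below the 2.93% and 3.29% in pdxJ.11p and the 4.55% and 4.89% in pdxJ.X3p. An exchange among the 12 would not set 2 libraries apart from the rest, so it cannot account for this pattern. Less oxygen at harvest remains a candidate explanation, since the cyo genes of the oxidase used with ample oxygen had medians of -1.35 and -1.02 while cydA and cydB, of the oxidase used at low oxygen, had medians of 3.90 and 3.75. Single cyo genes ranged from -2.92 to -0.32 and from -1.26 to -0.13. Synthesis genes were low as well, with medians of -2.45 and -2.67 for pyrimidines and -2.06 and -1.61 for branched-chain amino acids. Not all such lists moved: lysine and threonine genes had -0.35 and -0.07. The nutrient state of these cultures was not tested as a cause. The labels give no batch, date or oxygen level, so a separate batch of cultures with another growth state stays open.

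The his operon was higher in nanE.7, pdxJ.11p and pdxJ.X3p than in serB.wt. A dose of the introduced pdxJ transcript that acts alike in every variant is argued against as the sole source. In the 10-library fit pdxJ.X3p had more pdxJ counts than pdxJ.11p and a his median of -1.54 against it. Between pdxJ.11p and pdxJ.11m both were higher in pdxJ.11p, with a his median of 3.59. An effect of dose within the same variant was not tested, and protein levels were not measured. An amplified region reaching 10 kb past the operon on both sides is argued against by its 19 tested neighbours, whose highest median log2 fold change was 0.0277. The highest single neighbour stood at 0.73 in nanE.7, 0.81 in pdxJ.11p and 0.97 in pdxJ.X3p, and 0 passed. The medians join both sides, so a region reaching a shorter way or to a single side was not tested apart. An amplification of the operon alone stays open. A derepression of all amino acid synthesis to the same extent is argued against by the other 7 amino acid lists in the 10-library fit, whose highest median was 0.48, although there 7 of 12 branched-chain genes rose in pdxJ.X3p and 4 in nanE.7, and 5 of 24 sulfur genes rose in pdxJ.X3p (adjusted p = 0.212, 0.381 and 0.546 with an estimated correlation). What stays open is a change strongest at the operon, which may be an effect of the variant proteins or a mutation at the operon, and these reads per gene cannot separate them.

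Counts of serB appeared in all 10 libraries outside serB.wt. Reads assigned to the wrong library of the run are argued against, since the lowest serB count was 2.28 times the largest that the nanE counts outside nanE.7 would allow. A transcribed chromosomal serB, or a remainder of it, is a candidate explanation, since the ratio of serB to radA of the same operon had a median of 0.776 and ranged from 0.611 to 0.971. The labels state no serB deletion, and counts per gene do not show which part of the gene was read.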

How the results depend on the processing

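The fits without the libraries numbered 3 were chosen after the data had been seen, and the other alternatives of this paragraph beforehand. Scaling by DESeq2 size factors, no filter and a minimum count of 50 left every gene count within 1.5 times its main value and kept the his medians. For counts of changed genes, in the order nanE.7, pdxJ.11p, pdxJ.X3p and pdxJ.11m against serB.wt, pdxJ.11p against pdxJ.11m, nanE.7 against pdxJ.11p, pdxJ.X3p against pdxJ.11p, and genes shared by the first 3, the main values were 17, 12, 13, 9, 8, 8, 1 and 3. The DESeq2 Wald test gave 33, 20, 25, 15, 14, 11, 2 and 11. In a single simulated set of 12 libraries for nanE.7 against serB.wt, 13 of its 127 calls were false, against 4 of 103 for edgeR. That set gave every library the wider spread that the libraries numbered 3 bring. With 10 simulated libraries 2 of 160 DESeq2 calls and 4 of 187 edgeR calls were false. The library number as a block gave 217, 126, 185, 140, 44, 55, 23 and 62; numbers 1 and 2 showed no pairing, so the block mainly fits the libraries numbered 3. The 10 libraries gave 244, 152, 207, 154, 42, 57, 32 and 71 with edgeR and 129, 95, 104, 80, 25, 44, 25 and 39 with DESeq2. Fits of only the groups compared gave 12, 163, 223, 5, 0, 2, 35 and 9; at the count of 0 in edgeR 67 genes had an unadjusted p under 0.05 and DESeq2 on all 12 libraries called 14. Without serB, nanE and pdxJ the count for nanE.7 against pdxJ.11p was 5: nanE and pdxJ could no longer be called, and csgA lost its call. Leaving out each library in turn gave 9 to 16, 2 to 10, 4 to 7, 7 to 12, 4 to 9, 2 to 3, 1 to 1 and 1 to 6. The his operon median of pdxJ.11m against serB.wt, 0.58, lost its camera call with an estimated correlation (0.58), with the block (0.22), in the 10 libraries (0.20), without pdxJ.11m replicate 3 (0.19) and without serB.wt replicate 1 (0.42). It was 0.19 in the 10 libraries with DESeq2, where camera was not run, and ranged from 0.19 to 0.73 with a library left out. That of pdxJ.11p against pdxJ.11m was 3.14, and 3.60 in the 10 libraries with DESeq2. Of 233 single-gene results 58 were called. Of 3115 alternatives to these results 0 reversed direction with a call in the main or the alternative fit. A change of sign in a gene called in neither fit was not counted as a reversal. With libraries left out, calls held in 184 cases and were lost in 82. Except where stated, the cause was not tested. In simulated data the 12-library fit found 13.0% of changes of 1 log2 unit for nanE.7 against serB.wt, and 81.1% of those of 2 units. The 10-library fit found 80% and 95.4%, so the low share with 12 libraries does not come from depth alone.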

Other observations

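The 6 gene lists of these paragraphs were chosen after the data had been seen, from genes that stood out. Neither their directions nor their camera and Fisher p-values are therefore independent evidence. The fits are those without the libraries numbered 3 unless stated. Genes of fatty acid breakdown (fadA, fadB, fadE, fadJ and others) were higher against serB.wt: 5 of 8 rose in nanE.7 (median 0.77, adjusted p = 0.0418 with an estimated correlation, Fisher's exact test p = 0.000136), 4 in pdxJ.11p (adjusted p = 0.0895 with an estimated correlation), 5 in pdxJ.X3p (adjusted p = 0.0245) and 5 in pdxJ.11m (adjusted p = 0.0142). With all 12 libraries the medians were 0.27 in nanE.7, 0.54 in pdxJ.11p, 0.62 in pdxJ.X3p and 0.20 in pdxJ.11m, against 0.77, 0.54, 0.64 and 0.58 without number 3, and 0 of 8 genes passed the edgeR test in these comparisons, in which 107 to 293 genes had an unadjusted p under 0.05 and DESeq2 called 15 to 33. In the libraries numbered 3 all 8 genes were lower than in the mean of libraries 1 and 2, with medians of -2.63 in nanE.7 and -2.44 in pdxJ.11m. Every variant group was set against the same 2 serB.wt libraries. Higher levels in the variants thus cannot be told from a lower level in the serB.wt cells. Genes for taurine and alkanesulfonate use, which supply sulfur when sulfate is short, rose in pdxJ.11m against serB.wt, 5 of 8 (median 2.08, adjusted p = 0.0936 with an estimated correlation, Fisher's exact test p = 1.43e-05), and 3 fell in pdxJ.11p against pdxJ.11m (adjusted p = 0.0823 with an estimated correlation). With all 12 libraries the adjusted p with an estimated correlation was 0.0912 and 0.0361, and none of these genes passed.

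Cell surface genes also differed. All 6 measured curli genes rose in pdxJ.11m against serB.wt (median 1.35, adjusted p = 0.00469 with an estimated correlation), 4 rose in pdxJ.X3p, and 5 fell in nanE.7 against pdxJ.11p. With all 12 libraries 0 of 6 passed the edgeR test in pdxJ.11m and in pdxJ.X3p (adjusted p = 0.122 and 0.46 with an estimated correlation), in which 139 and 130 genes had an unadjusted p under 0.05 and DESeq2 called 15 and 25. In library 3 of pdxJ.11m all 6 genes were lower than in the mean of libraries 1 and 2, and the same difference in nanE.7 had a median of -1.05. All 6 fold changes against serB.wt were still positive with library 3 kept, with medians of 0.85 in pdxJ.11m and 0.75 in pdxJ.X3p, and 2 and 0 genes passed adjusted over the list alone. All 20 colanic acid genes fell in nanE.7 against serB.wt (median -1.96, adjusted p = 0.00102 with an estimated correlation), where 4 passed with all 12 libraries. For this list library 3 had medians of -1.29 in nanE.7 and -2.36 in pdxJ.11m against libraries 1 and 2 of its group. Genes of type 1 fimbriae, adhesive fibres of the cell surface, fell in pdxJ.11p against pdxJ.11m, 2 of 5 (median -1.04, adjusted p = 0.0393 with an estimated correlation), and 2 rose in nanE.7 against pdxJ.11p (median 1.27, adjusted p = 0.011 with an estimated correlation). With all 12 libraries none passed, and the adjusted p with an estimated correlation was 0.0361 and 0.0395. With all 12 libraries the 6 phage shock genes had medians of -3.97 in pdxJ.X3p, -3.93 in pdxJ.11m, -2.60 in pdxJ.11p and -1.38 in nanE.7 against serB.wt. Since every variant group was lower, lower levels in the variants cannot be told from a raised level in the serB.wt cells.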
